A study of Mus musculus with 2 samples.

How the data were processed

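Full-length RNA reads of the left cerebral cortex were measured by PacBio long-read RNA sequencing in 2 libraries of B6NCrl mice, replicate 1 and replicate 2 of 1 untreated group that the labels describe as female controls. The labels name MODEL-AD, a consortium that builds mouse models of Alzheimer disease, as the source. They give a separate tissue sample and a separate biological replicate number for each library but the same donor identifier, and do not say whether the tissue came from separate animals. The sex field and the age field were left as not collected.

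The authors deposited, for each library, a table of raw read counts per transcript model and an annotation of those models. Per the notes deposited with each library, both were made from a filtered alignment on the mm10 genome with the GENCODE M21 annotation, without pooling of replicates. The deposited annotation names TALON, a program that sorts long reads into known and unannotated transcripts, as the source of unannotated models. The aligner and the versions of these tools are not given in the sources used here. The counts are whole numbers with no normalisation, and the deposited tables list only models with at least 1 read. Each model carries a class in the deposited table. Known models match an annotated transcript at every splice junction. Incomplete splice matches hold part of the junctions of an annotated transcript in order. Unannotated combinations join annotated splice donors and acceptors in a way that the annotation lacks, and models with an unannotated splice site use at least 1 donor or acceptor outside it. Genomic, antisense and intergenic models are the classes for reads that overlap a gene without matching its splicing, lie on the strand opposite a gene, or lie outside genes. The other deposited values used, read by their column names, were the number of exons and the length of each model.

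Reads were summed per annotated gene over all models of that gene, spike-ins kept in the total and out of the tests, and scaled to CPM, counts per 1000000 reads on annotated genes. Totals were 2259132 reads in replicate 1 and 2016725 in replicate 2, of which 97.4% and 97.1% lay on annotated genes. A gene without a read has an upper limit of 3 counts, or 1.36 CPM in replicate 1 and 1.53 in replicate 2. Intervals are 95% exact binomial (Clopper-Pearson) intervals. They and the limits cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

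Each gene with at least 20 reads over both libraries was compared by a 2-sided exact binomial test of the reads of replicate 1 among those of both, against the share of replicate 1 in the totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. Such tests compare these 2 libraries and not conditions. Their p-values account for counting error only and not for a spread between samples, which may be technical. The log2 ratio was computed with 0.5 added to each count. Gene lists fixed in advance, 21 in all, were compared by the ratio of their summed reads with its exact interval, and by the percentile of the median log2 ratio among 10000 random lists of the same size, drawn from the 100 genes nearest in mean level on each side. The summed reads were tested with the same exact test, adjusted over the 21 lists. Correlations across genes used log2 of CPM plus 1, and genes are not independent replicates.

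Spliced models of the libraries were matched by chromosome, strand and every intron. The share of the most abundant annotated transcript was taken among reads on annotated transcripts of its gene, in genes with at least 20 such reads in each library, and compared between libraries by a chi-square statistic with 10000 permutations of reads. Exon inclusion was the number of reads of models with the exact internal exon over those plus the reads of models with an intron that spans it, for annotated internal exons of 52 genes fixed in advance. Exons with a mean inclusion from 5 to 95% and at least 20 informative reads in each library are called alternative, and were compared by Fisher exact tests. Coordinates are 1-based on mm10.

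Genes are named by rules fixed in advance. Some genes that these rules would name are not reported here. The rules take the 20 genes with the highest mean, up to 4 members of each list with the highest mean (every member of the Alzheimer disease and sex lists), the 10 genes higher in each library with the largest log2 ratio past the threshold, the alternative exons, the 10 unannotated intron chains with most reads in both libraries, the 10 genes with most reads in which 2 transcripts each hold at least 25% in both libraries, the 5 genes with the smallest p for isoform usage, and genes that reach the closing section. No edgeR or DESeq2 test was possible with 1 group. Their TMM and median-of-ratios factors were used as alternative scalings.

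On simulated counts with the depths of these libraries and 11326 genes tested, the exact binomial test recovered 59.4% of 96 genes changed 2-fold and 92.9% of 99 genes changed 4-fold, with 6 false calls among 155. It made 0 calls among 11288 genes when nothing was changed. Simulated isoform changes of 30 percentage points were recovered in 82% of 200 genes among 4177 tested, with 0 false calls. Of 200 unchanged random lists of 10 genes, 4% fell outside the central 95% of the random lists. The simulated counts had no spread beyond counting, unlike the libraries themselves.

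Alternatives fixed before the data were examined were counting on known transcripts only, leaving out the genomic class, the TMM and median-of-ratios scalings, other read minimums, a 2-fold minimum, totals and class shares without mitochondrial genes, class shares without single-exon models, chain matching at other read minimums and within 5 bases, isoform shares over more model classes, exon inclusion over fewer model classes, and each library alone. Those added after the data were examined were giving each shared intron chain to 1 gene, 1000000 permutations for the genes with the smallest p, and each list without its most abundant member. No genome sequence was used here, so splice site motifs and sequence outside annotated transcripts were not examined. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.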

Results

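The data are read counts per transcript model from PacBio long-read RNA sequencing of the left cerebral cortex of B6NCrl mice, in 2 libraries of 1 control group. The libraries held 2259132 reads in replicate 1 and 2016725 in replicate 2, and the median length of the transcript model behind a read was 2432 and 2394 bases. Values below are means over the 2 libraries with their SD (n = 2) unless a library is named. The design has no treatment, so the libraries answer which genes and transcript forms the control cortex holds and how far its replicates differ.

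The most abundant gene was Hspa8, which encodes a constitutive heat shock chaperone (ENSMUSG00000015656.17, chromosome 9, 40800984 to 40810087), at 14691 ± 1304 CPM (counts per 1000000 reads on annotated genes). The creatine kinase gene Ckb followed at 10560.2 ± 131, the myelin gene Mbp at 7619 ± 1176 and Ndrg4 at 5109 ± 31.5. Others of the 20 most abundant genes were the elongation factor gene Eef2 (5061 ± 440), the lipid carrier gene Apoe (5007 ± 279), the tubulin gene Tuba1a (4746 ± 316), the actin gene Actg1 (4739 ± 23.7), the ferritin gene Fth1 (4551 ± 659) and the synaptic gene Snap25 (4258 ± 337). The remaining members, from Cpe at 3985 ± 733 to Tubb2a at 2744 ± 267, included Eef1a1, Pkm, Aldoa, Atp5a1, Ubb, Eif4a2, Trf and Rpl3. The 20 genes took 9.90% of the reads on annotated genes in replicate 1 and 10.1% in replicate 2. At least 1 read was found for 18550 genes in replicate 1 and 18390 in replicate 2, and for 18215 in replicate 1 after thinning to the total of replicate 2. Of the 20492 genes with a read in either library, 16448 were found in both, and the 4044 found in a single library had a median of 1 read. A mean above 10 CPM was reached by 9110 genes and above 1000 CPM by 101. Protein-coding genes held 98.4% and 98.2% of the reads on annotated genes.

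Markers of excitatory neurons summed to 1182 ± 27.0 CPM, led by Arpp21 (575 ± 19.0) and Camk2a, the alpha subunit of a calcium-dependent kinase of the synapse (376 ± 3.50). Inhibitory neuron markers summed to 1145 ± 51.2, led by the GABA-synthesising enzyme genes Gad1 (756 ± 38.5) and Gad2 (169 ± 29.9). Cortical layer markers summed to 818 ± 48.0, of which the calcium-binding protein gene Calb1 held 53.1% of the summed mean CPM, with Bcl11b at 83.0 ± 6.18, Cux1 at 67.0 ± 2.82 and Etv1 at 50.9 ± 2.59. Synaptic genes summed to 10509 ± 97.2, led by Snap25, the synaptic vesicle gene Syp (1613 ± 82.9), Camk2b (910 ± 23.3) and the glutamate receptor subunit gene Gria2 (860 ± 114). Genes used as markers of the striatum, the nucleus below the cortex, summed to 2284 ± 33.9, more than either neuron list, with the dopamine-signalling phosphoprotein gene Ppp1r1b at 808 ± 58.0, the enkephalin gene Penk at 428 ± 29.6 and Rgs9 at 253 ± 13.1. Some of these genes are also expressed in cortical neurons. Sums of lists, here and below, depend on the number and level of their members and do not measure the amount of a cell type or region. Hippocampus markers summed to 35.8 ± 6.56 and thalamus markers to 41.1 ± 12.6.

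Oligodendrocyte markers had the highest sum of the cell type lists at 15692 ± 1978 CPM, with Mbp, the iron carrier gene Trf (3084 ± 188) and the myelin gene Cnp (1454 ± 118) among the most abundant members. Astrocyte markers summed to 6360.4 ± 129, with the aldolase gene Aldoc at 2670 ± 141 and the glutamate transporter gene Slc1a3 at 808 ± 26.1. Microglia markers reached 1074 ± 85.3 (Csf1r 136 ± 26.5), endothelial markers 698 ± 124 (Cldn5 252 ± 81.2, Itm2a 199 ± 10.4), oligodendrocyte precursor markers 315 ± 24.6 (Olig1 153 ± 4.46) and mural cell markers 235 ± 21.1 (Rgs5 116 ± 12.5). The stress and RNA quality list summed to 1118 ± 64.6, with Hsph1 at 735 ± 88.2 and the nuclear RNA Malat1 at 127 ± 24.1. Mitochondrially encoded mRNAs took 463 ± 115, with mt-Co1 at 68.2% of the summed mean CPM.

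Of the Alzheimer disease related genes, all 22 had reads. Apoe was followed by App, which encodes the amyloid precursor protein (1942 ± 469 CPM), the cathepsin gene Ctsd (1067 ± 77.1), the cystatin gene Cst3 (1026 ± 92.0), Clu (598 ± 6.24), Bin1 (375 ± 22.1), Mapt, which encodes tau (215 ± 15.2), and the beta-secretase gene Bace1 (151 ± 14). Sorl1 stood at 97.9 ± 12, and the gamma-secretase genes Ncstn, Aph1a, Psen2 and Psenen at 66.9 ± 5.69, 13.9 ± 1.57, 10.2 ± 2.90 and 7.21 ± 0.0839. Picalm stood at 30.3 ± 1.15, Adam10 at 16.7 ± 1.72, the microglial receptor gene Trem2 at 11.4 ± 3.33 and Abca7 at 9.11 ± 0.607. Plcg2, Cd33 and Cd2ap, from 2.81 to 3.89 CPM, had too few reads to be tested. App was 1.41-fold higher in replicate 1 (5005 against 3153 reads, adjusted p 6.03e-50, exact binomial test), and Apoe and Ctsd were 1.08-fold and 1.11-fold higher there (adjusted p 1.78e-06 and 0.0242). Cst3 was lower in replicate 1, at 0.881 times its level in replicate 2 (adjusted p 0.00205). Over all genes tested, 3 members were higher in replicate 1 and 1 in replicate 2, and the counts adjusted over the list alone were 3 and 1.

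Xist, the RNA of the inactive X chromosome, had 39 reads in replicate 1 and 33 in replicate 2, and its antisense gene Tsix 2 and 5. Most of these reads lay on models of the genomic class, as the mean of the sex list went from 19.0 CPM to 1.03 without that class and to 0.336 on known transcripts only. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no listed model in either library, which allows up to 1.36 and 1.53 CPM. Spike-in RNAs took 0.0199% of reads in replicate 1 (95% interval 0.0181 to 0.0218%) and 0.0317% in replicate 2 (0.0293 to 0.0343%).

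Comparing the replicates asks how far 2 libraries of the same tissue and group differ. Several genes of strong tissue restriction were found almost entirely in replicate 1. Gh and Prl, the growth hormone and prolactin genes of the pituitary, had 393 and 415 reads in replicate 1 against 0 and 1 in replicate 2, at least 117-fold for Gh against a limit of 3 counts per library and 369-fold for Prl (95% interval 65.9 to 14615). Omp, the marker gene of olfactory receptor neurons, had 112 against 5 reads (19.9-fold, 8.29 to 62.6). The reverse was seen for Ttr, the transthyretin gene of the choroid plexus, with 7 reads in replicate 1 and 982 in replicate 2 (158-fold, 76.3 to 393). Egr2, an activity-induced transcription factor gene, had 9 against 43 reads (5.37-fold, 2.58 to 12.5).

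The other genes named as higher in replicate 1 were Bpifb9b (74 against 0 reads, at least 21.9-fold), Mir467f (50 against 0, at least 14.8-fold), Gm27221 (42 against 0, at least 12.5-fold), Bpifb9a (33 against 0, at least 9.78-fold), Pcdhga3 (30 against 0, at least 8.90-fold), Klhl10 (79 against 1, 70.3-fold, 12.3 to 2810.3) and Cyp2a5 (43 against 2, 19.1-fold, 4.98 to 163). On known transcripts only, Cyp2a5 had 38 reads against 0, at least 11.2-fold, Bpifb9b 57 against 0 and Bpifb9a 23 against 0. The miRNA gene Mir467f had 8 against 0 there and Pcdhga3 2 against 0, while Gm27221 and Klhl10 had no such read in either library. Mir467f is annotated only from 69635400 to 69635519 on chromosome 11, far shorter than the median model, so its reads may not measure the miRNA. Those named as higher in replicate 2 were Usp50 (32 against 0 reads, at least 12-fold), Gm28496 (20 against 1, 22.5-fold, 3.60 to 932), 4930520O04Rik (21 against 2, 11.8-fold, 2.89 to 104), Hgs (170 against 18, 10.6-fold, 6.52 to 18.3), Zfp454 (57 against 9, 7.12-fold, 3.50 to 16.4), Zfas1 (17 against 3, 6.37-fold, 1.84 to 33.9), Gm21955 (20 against 4, 5.62-fold, 1.88 to 22.6) and Gm43738 (45 against 12, 4.22-fold, 2.19 to 8.76). On known transcripts only, Usp50, Gm28496 and Gm43738 had no read in either library, and Hgs had 4 reads and 4930520O04Rik 1 in each. Replicate 2 against replicate 1, Zfp454 had 4 against 3 such reads, Gm21955 2 against 4 and Zfas1 16 against 3. Hgs is uncertain because a second annotated gene of that symbol, ENSMUSG00000116045.1, covers the same locus and had 287 reads in replicate 1 and 68 in replicate 2, the opposite direction to ENSMUSG00000025793.16. Where an identical intron chain was given to 1 gene in both libraries, Gm27221 and Gm43738 changed sign, and Pcdhga3, Hgs and Zfp454 no longer passed the threshold. Reads of the other library at the same positions on other genes also ended the calls of Klhl10, 4930520O04Rik and Gm21955, and Zfas1 did not pass where genes with fewer reads entered the adjustment. Bpifb9a and Bpifb9b are neighbouring members of a gene family, and their counts could share reads.

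Across all genes, 439 of 11341 tested differed between the libraries (3.87%), 234 higher in replicate 1 and 205 in replicate 2, by exact binomial tests with Benjamini-Hochberg adjustment. At least 2-fold differences were found in 95 of them, 53 higher in replicate 1 and 42 in replicate 2. The level of genes correlated at Pearson r 0.974 and Spearman rho 0.949 across 20492 genes, which are not independent replicates. The chi-square of the counts over its 11340 degrees of freedom was 2.67, so the libraries differed by more than sampling noise, which a pair of technical libraries of 1 sample could also do. Among the 2088 genes above 100 CPM, the SD of the log2 ratio was 0.26.

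**Figure D1:**
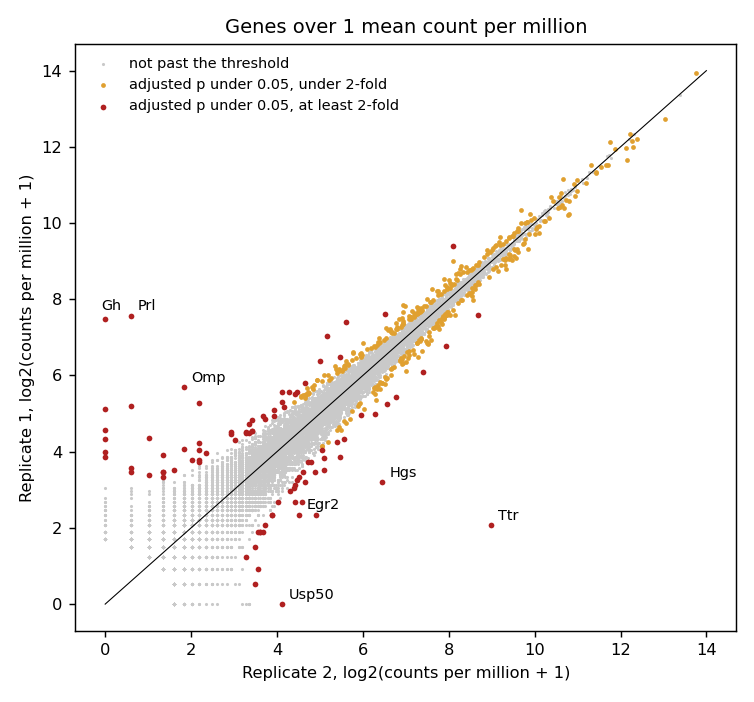
Level of each gene in replicate 2 (horizontal) and replicate 1 (vertical) as log2 of CPM plus 1, for genes above a mean of 1 CPM. Orange points passed the exact binomial test with a ratio under 2-fold and red points with at least 2-fold, and Gh, Prl and Ttr lie farthest from the diagonal among the genes named in the plot.

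Immediate early genes, which neurons induce within minutes of activity, were lower in replicate 1, at 0.488 times their summed level in replicate 2 (95% interval 0.456 to 0.521). Of 10 members tested, 7 were higher in replicate 2 over all genes tested and 8 when adjusted over the list alone, which also put 1 higher in replicate 1. Junb had 421 reads in replicate 1 and 803 in replicate 2, Arc 239 and 479, Egr1 263 and 347, and Dusp1 148 and 329. The median log2 ratio of the list was -1.14, below all of the 10000 random lists matched on level.

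Oligodendrocyte markers were also lower in replicate 1, at 0.836 times replicate 2 (0.824 to 0.849), with 6 of 12 members higher in replicate 2 and none in replicate 1 (8 adjusted over the list alone). Mbp stood at 0.803 times and Trf at 0.917. Mitochondrially encoded mRNAs stood at 0.702 times replicate 2 (0.640 to 0.769), with mt-Co1 the only member of 9 tested to pass the threshold, also when adjusted over the list alone. Blood markers stood at 0.337 times (0.227 to 0.491), with 1 of 3 members tested higher in replicate 2 and 2 when adjusted over the list alone. These were globin genes with near-identical copies, so the counts of Hbb-bs (12 against 40 reads), Hba-a1 (9 against 21) and Hba-a2 (11 against 17) are uncertain per gene. Choroid plexus and ependyma markers stood at 0.0296 times (0.0204 to 0.0417), with 1 of 3 members higher in replicate 2 and 2 adjusted over the list alone. Ttr held 94.0% of the summed mean CPM of that list, with 7 of its 34 reads in replicate 1 and 982 of its 1021 in replicate 2, and without Ttr the ratio was 0.616 (0.363 to 1.03), no longer past the threshold.

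The summed endothelial, meningeal fibroblast and microglia lists were higher in replicate 1. Endothelial markers stood at 1.29 times replicate 2 (1.19 to 1.39), with Cldn5, a tight junction gene, at 680 against 380 reads the only member of 8 past the threshold, also adjusted over the list alone. Meningeal fibroblast markers stood at 2.19 times (1.65 to 2.92), with 1 of 3 members tested higher in replicate 1 and 2 adjusted over the list alone. They summed to 58.6 ± 30.9 CPM, with Slc6a13 at 85 against 32 reads and the decorin gene Dcn at 41 against 16. Microglia markers stood at 1.12 times (1.05 to 1.19), with 2 of 11 members higher in replicate 1 and 4 adjusted over the list alone, among them Csf1r at 341 against 230 reads (adjusted p 0.0347 over all genes). The median log2 ratio lay at percentile 99.99 of the random lists for microglia, 99.97 for meningeal (3 members tested) and 98.7 for endothelial markers. The endothelial value does not stand apart, as Alzheimer disease related genes lay at 98.6, astrocyte markers at 98.2 and synaptic genes at 97.2.

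The sums of the neuronal lists differed little, while some of their members differed more. Excitatory neuron markers stood at 0.968 times replicate 2 (0.915 to 1.02) and synaptic genes at 1.01 (0.994 to 1.03), neither past the threshold for the sum. The synaptic sum did pass without its most abundant member (1.10) and with median-of-ratios scaling (1.03). No excitatory marker of 9 passed the test in either way of adjusting, while 3 synaptic genes of 19 were higher in replicate 1 and 1 in replicate 2 (6 and 1 adjusted over the list alone). Striatum markers stood at 1.02 (0.981 to 1.06), and at 0.985 on known transcripts only, neither past the threshold, with 1 of 9 higher in replicate 1, and 1 in each direction adjusted over the list alone. Their sum passed the threshold without the genomic class and without the most abundant member, at 1.09 in both. Inhibitory neuron markers stood at 1.07 (1.01 to 1.13, 1 member higher in each library, the same count adjusted over the list alone), astrocyte markers at 1.03 (1.00 to 1.05, 2 members higher in each library, and 2 and 3 adjusted over the list alone) and cortical layer markers at 1.09 (1.02 to 1.16), where only Calb1 passed, under both adjustments. Alzheimer disease related genes stood at 1.10 times replicate 2 (1.08 to 1.12).

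The sums of 14 of the 21 lists passed the threshold. Stress and RNA quality genes stood at 1.09 (1.02 to 1.15, 1 member higher in replicate 1, and 1 in each direction adjusted over the list alone), thalamus markers at 1.55 (1.13 to 2.15, none over all genes and 1 higher in replicate 1 adjusted over the list alone), oligodendrocyte precursor markers at 1.12 (1.00 to 1.25, likewise 0 and 1) and hippocampus markers at 1.30 (0.927 to 1.83, likewise 0 and 1). Mural cell markers stood at 1.14 (0.999 to 1.29) and the sex list at 0.960 (0.602 to 1.53), with no member past either adjustment. With the most abundant member of each list left out, an alternative added after the data were examined, the call ended for cortical layer (0.966), stress (0.917), inhibitory (1.05) and thalamus markers (1.38), and the cortical layer and stress lists changed direction. Under TMM scaling the calls of the astrocyte (1.02) and inhibitory lists (1.06) ended, and that of the astrocyte list also ended on known transcripts only (1.02).

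**Figure D2:**
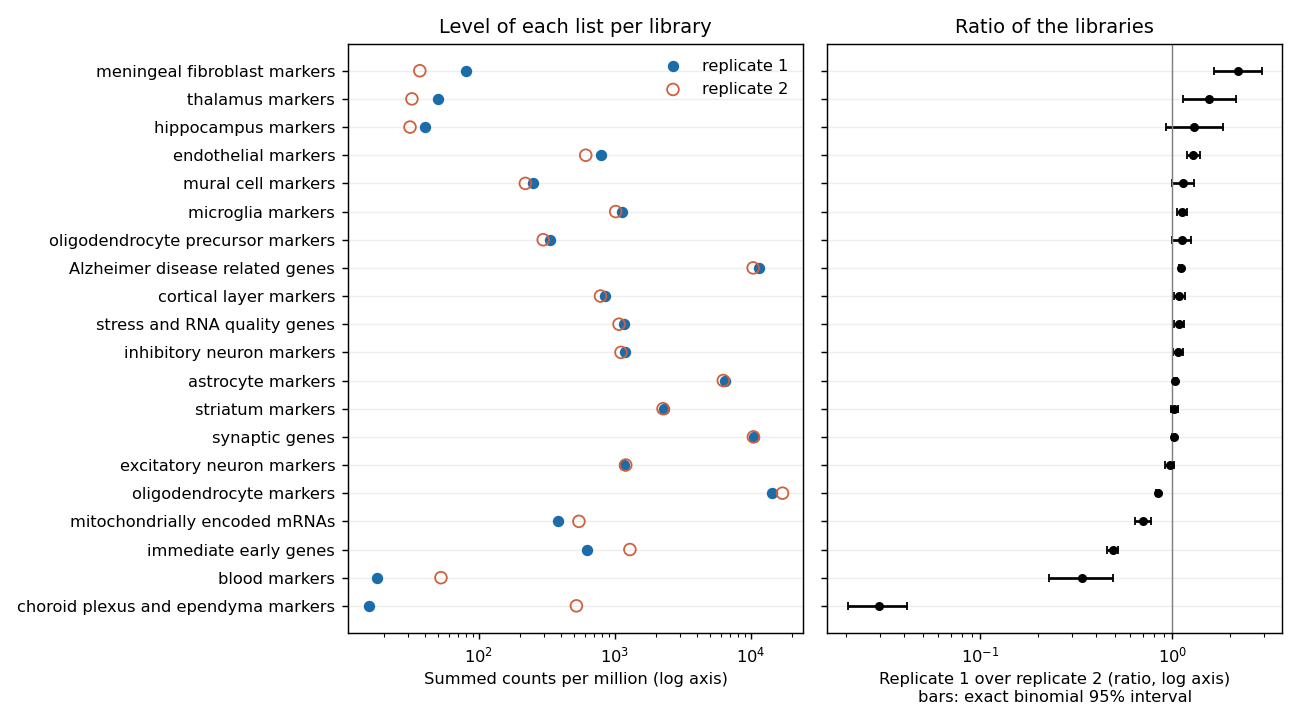
Left, summed CPM of each gene list in replicate 1 (filled) and replicate 2 (open) on a log axis. Right, the ratio of replicate 1 to replicate 2 with its exact binomial 95% interval, from 0.0296 for choroid plexus and ependyma markers to 2.19 for meningeal fibroblast markers.

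Known transcripts took 74.1 ± 0.526% of the reads, incomplete splice matches 9.42 ± 0.0644%, unannotated combinations of annotated splice sites 6.8 ± 0.101%, models with an unannotated splice site 3.86 ± 0.0375%, genomic models 3.17 ± 0.207%, antisense models 2.35 ± 0.220% and intergenic models 0.282 ± 0.0243%. Of the reads on incomplete matches, 54.1 ± 1.25% were suffixes, which lack the 5' part of the annotated transcript, and 32.8 ± 2.05% prefixes. Replicate 1 held 212459 models and replicate 2 204072, of which 63.0% and 63.4% rested on 1 read. An identical intron chain was present in the other library for 82.7 ± 1.77% of known spliced transcripts, 42.5 ± 1.46% of unannotated combinations and 23.7 ± 1.48% of models with an unannotated splice site. With at least 5 reads in the library of origin, these shares were 99.5 ± 0.361%, 98.1 ± 0.498% and 97.2 ± 0.131%. Of 74085 shared chains, 309 were assigned to different genes in the libraries, with 1274 reads in replicate 1 and 1267 in replicate 2.

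**Figure D3:**
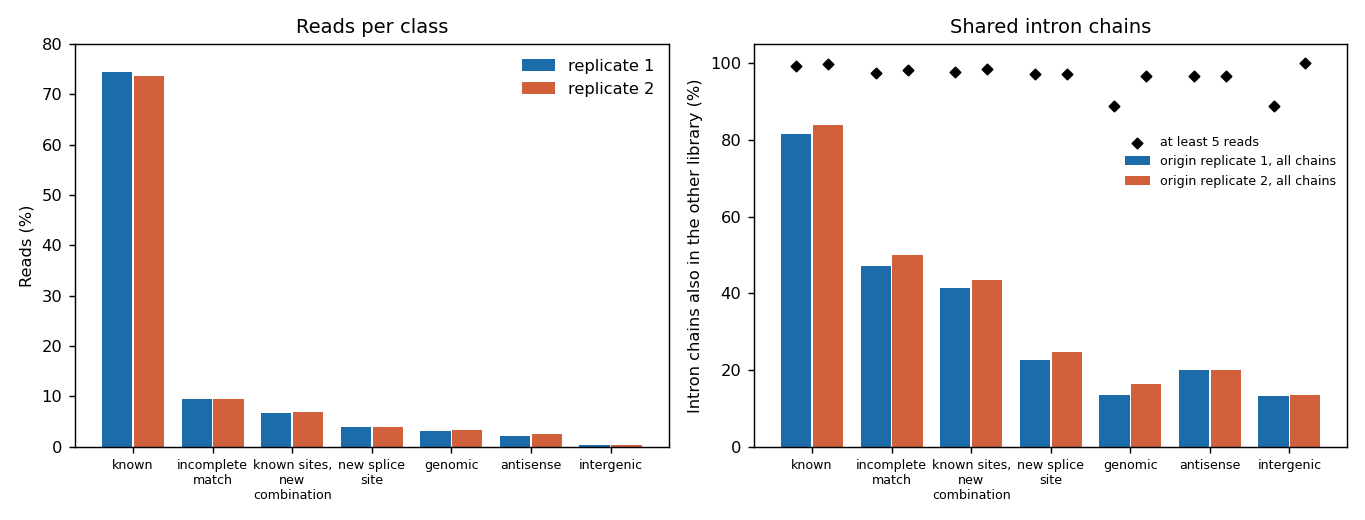
Left, percent of reads in each transcript class for replicate 1 (blue) and replicate 2 (orange). Right, percent of spliced models of each class whose intron chain is also in the other library, for all chains (bars) and for chains with at least 5 reads in the library of origin (diamonds).

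Several abundant genes were carried mostly by an intron chain that the annotation lacks. Apbb1, which encodes an adaptor that binds the amyloid precursor protein, had the most reads on such a chain, 1881 ± 199 per library and 59.0 ± 2.73% of its spliced reads of all classes, incomplete matches included, over 13 introns from 105559051 to 105581134 on chromosome 7. Oaz1 and Oaz2, the ornithine decarboxylase antizyme genes, had 1606 ± 80.6 and 1316 ± 16.3 reads, or 96.6 ± 0.246% and 91.8 ± 1.58% on the same basis. Neither chain holds an intron outside the annotation of its gene. Each gene has 2 annotated introns under 10 bases, the shortest of 1 base, which the chain lacks. These chains may thus differ from annotated transcripts only in such a short gap, which was not tested. The proenkephalin gene Penk had 865 ± 138 reads on its chain (98.6 ± 0.307%), with an intron of 488 bases on chromosome 4 (4138147 to 4138634) whose start lies 1 base from that of the annotated intron of 489 bases. The dynactin gene Dctn2 had 1357 ± 55.9 reads (85.4 ± 0.970%), with the start of an intron of 7221 bases shifted by 10 bases at 127267493 on chromosome 10.

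The other chains with most reads, with shares again of the spliced reads of all classes, were those of Rapgef4 (1256 ± 275 reads, 40.9 ± 1.51%), Chmp1a (808 ± 31.8, 91.4 ± 1.11%), Cct6a (774 ± 38.9, 88.1 ± 2.09%), Sept7 (756 ± 29.7, 59.1 ± 0.844%) and Aplp2 (667 ± 113, 62.5 ± 0.213%). Those of Rapgef4, Chmp1a, Cct6a and Sept7 each held 1 intron outside the annotation of the gene, of 37470, 3542, 50376 and 12694 bases, while those of Apbb1 and Aplp2 held none. In 386 of 7114 genes with at least 20 complete spliced reads per library (5.43%), an unannotated chain was the most abundant in both libraries, and in 142 (2.00%) it held over 50% in both. Splice motifs of these introns were not examined.

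Among reads on annotated transcripts alone, the median share of the most abundant transcript was 97.7 ± 0.135% across 6340 genes, of which 1947 had reads on 1 annotated transcript only and so stood at 100% by construction. In the 4393 genes with more than 1 it was 92.1 ± 0.133%. The share was over 90% in 68.4% of the 6340 genes, in 34.6% of 7334 genes with unannotated complete chains included and in 17.0% of 8803 genes over all models. The most abundant annotated transcript was the same transcript in both libraries in 97.9% of the 6340 genes. This value and the 68.4% include the 1947 genes with reads on 1 annotated transcript, which are counted in both by construction. A pair of transcripts with at least 25% each in both libraries was found in 681 genes (10.7%). The genes of this kind with most reads were Cnp (71.8 ± 1.10% and 28.1 ± 1.07%), Pja2 (67.9 ± 0.169% and 31.5 ± 0.120%), Eif4h (61.7 ± 0.733% and 38.3 ± 0.767%), Ndrg2 (69.4 ± 3.09% and 30.6 ± 3.09%), Cnbp (48.8 ± 0.528% and 32.7 ± 1.43%), Hmgcs1 (56.3 ± 2.51% and 43.7 ± 2.51%), Hspa5 (61.2 ± 0.918% and 38.7 ± 1.04%), Tcf25 (48.4 ± 0.543% and 39.5 ± 1.76%), Gria2 (56.1 ± 3.52% and 33.5 ± 4.87%) and Zcchc18 (52.2 ± 1.12% and 37.3 ± 1.34%).

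On annotated transcripts, no gene of 4393 tested differed in isoform usage between the libraries after adjustment, and 204 had an unadjusted permutation p under 0.05. With unannotated complete chains included 122 genes of 7067 differed, and over all models 35 of 8637. The 5 genes with the smallest p, 1e-04, which is the smallest that 10000 permutations can give, had an adjusted p of 0.0879. They were Rtn1 (Rtn1-201 at 64.0% in replicate 1 and 73.9% in replicate 2), Prkcb (Prkcb-202 at 91.9% and 78.9%), Oxr1 (Oxr1-205 at 53.8% and 72.5%), Sgk1 (Sgk1-201 at 46.1% and 64.9%) and Grsf1, where Grsf1-202 held 43.7% in replicate 1 and 80% in replicate 2. With 1000000 permutations, run after this result was seen, 6 genes differed, with a smallest adjusted p of 0.00220. The smallest p of the planned number of permutations thus limited the test.

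Alternative exons of neuronal and glial genes were measured at 76 positions in 30 of the 52 fixed genes. The mutually exclusive 118-base exons of Snap25 on chromosome 2 were included in 7.47 ± 0.716% (136769743 to 136769860) and 92.5 ± 0.692% of reads (136770057 to 136770174). The mutually exclusive 167-base exons of the pyruvate kinase gene Pkm on chromosome 9 were included in 90.8 ± 0.527% (start 59675029) and 9.16 ± 0.468% (start 59675568). The 115-base exon pair of the AMPA receptor genes, known as flip and flop, was included in 65.2 ± 2.64% and 32.0 ± 2.06% of Gria1 reads (starts 57309769 and 57310608, chromosome 11), 36.1 ± 5.31% and 64.1 ± 4.98% of Gria2 reads (80690404 and 80691320, chromosome 3) and 23.1 ± 6.40% and 77.4 ± 5.59% of Gria3 reads (41654810 and 41669501, chromosome X). The values of Gria3 depended on the models counted, at 3.40% and 97.0% without incomplete matches and 1.5% and 99.2% on known transcripts only.

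In Mapt on chromosome 11, the 87-base coding exons at 104287123 and 104289908 were included in 25 ± 2.09% and 16.8 ± 0.384% of reads and the 759-base exon at 104298498 in 6.45 ± 0.106%. On known transcripts only, the 759-base exon was included in 0% of reads, with 320 reads of replicate 1 and 250 of replicate 2 that skip it. Outside the range for alternative exons, and chosen after its value was seen, the 93-base exon of Mapt at 104318157 was included in 99.6 ± 0.622%. The 57-base and 168-base exons of App on chromosome 16 (85040251 and 85043576), chosen in the same way, were included in 1.99 ± 0.386% and 4.33 ± 0.669%. In the NMDA receptor gene Grin1 on chromosome 2, the 63-base exon at 25311343 was included in 29.9 ± 2.99% and the 111-base exon at 25294438 in 30.9 ± 0.317%. The light chain genes of clathrin, Clta and Cltb, included their 54-base exons in 86.2 ± 0.574% and 79.9 ± 1.99%. Bin1 held 6 such exons, from 28.6 ± 0.360% for a 108-base exon at 32430750 to 65.0 ± 4.04% for the 72-base exon at 32431671 on chromosome 18. In myelin genes, the 45-base exon of Mag at 30900352 on chromosome 7 was included in 78.1 ± 0.991% and the 123-base exon of Mbp at 82578936 on chromosome 18 in 11.7 ± 0.370%. Some of these values depended on the models counted. Known transcripts only gave 95.9% for the Mag exon and 16.8% for both 87-base exons of Mapt. The Bin1 exons at 32430750 and 32431671 were then at 36.9% and 57.4%. Values stayed close for the 63-base and 111-base exons of Grin1 (30.5% and 30.4%), Clta (86.2%), Cltb (80.2%) and Mbp (11.8%).

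Of the 76 exons, only the pair of Gria2 differed between the libraries by Fisher exact tests, at 39.8% (95% interval 37.5 to 42.1%) in replicate 1 and 32.3% (29.7 to 35.0%) in replicate 2 for the exon at 80690404, and 60.6% and 67.6% for the exon at 80691320 (adjusted p 0.00193 and 0.00324). On known transcripts only, a 79-base exon of Tpm3 at 90091013 on chromosome 3 also differed, at 20.6% and 33.5% (adjusted p 0.0434, Fisher exact test), while over all models it was at 8.55% and 11.3% (adjusted p 0.457). An unadjusted p under 0.05 was found for 7 exons. The median SD between the libraries was 1.85 percentage points.

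**Figure D4:**
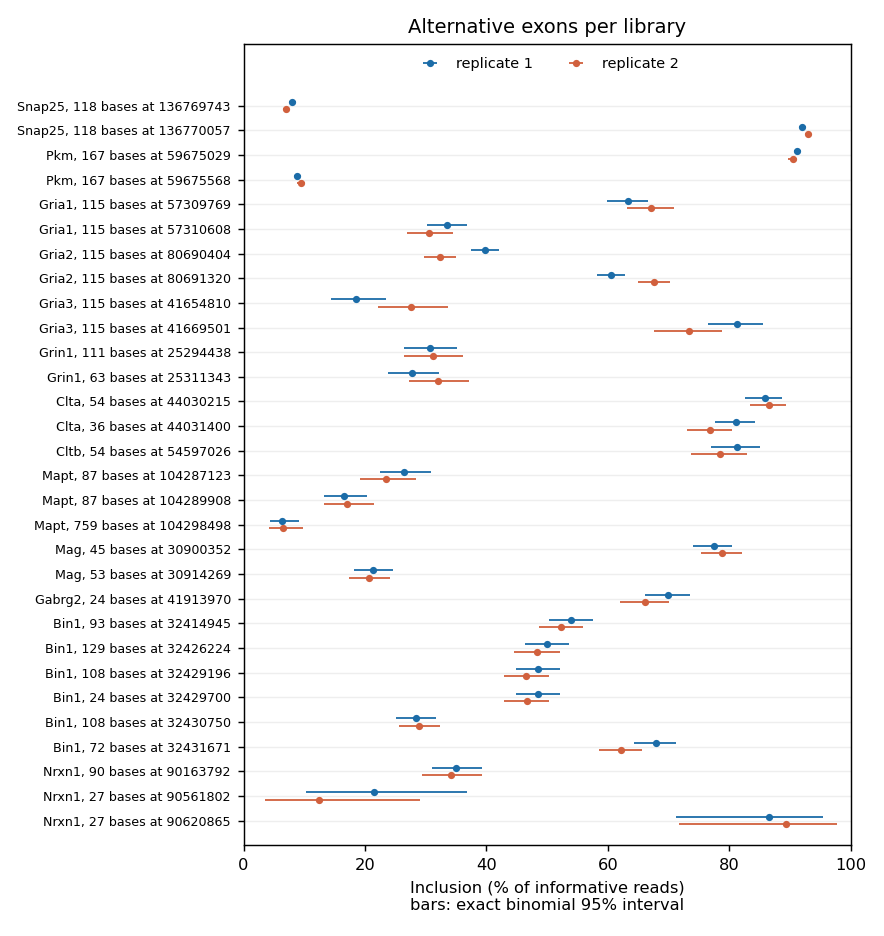
Inclusion of alternative exons in percent of informative reads for replicate 1 (blue) and replicate 2 (orange), with exact binomial 95% intervals, for exons of 13 genes named by length and start. The intervals of the replicates do not overlap for the exon pair of Gria2.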

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

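The comparison with the most abundant genes and the comparison of A-rich ends with random positions were chosen only after the result was seen, and the bounds for the other tests of locus ends were written before, with the wording narrowed afterwards to loci that end inside exons.

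Reads on unannotated loci on the strand opposite a gene are counted above only in the shares and shared chains of transcript classes and enter no comparison of genes, isoform usage or exons, and the 5 loci with most reads lie far above the 3 counts that a value of 0 allows. The locus opposite the astrocyte glutamate transporter gene Slc1a2 (chromosome 2, 102777584 to 102785996) had a mean of 777 ± 141 reads per library (SD, n = 2), and Slc1a2 itself had 797 and 643 reads in replicate 1 and replicate 2. The locus opposite Snhg11 (chromosome 2, 158381590 to 158384917) had 770.5 ± 85.6 reads, against 507 and 523 reads on Snhg11, and that opposite the microtubule-associated protein gene Map1b (chromosome 13, 99421446 to 99424415) 755 ± 96.2, below the 2246 and 1599 reads on Map1b. The locus opposite AI593442 (chromosome 9, 52673042 to 52676802) had 646 ± 28.3 reads, against 138 and 115 reads on AI593442. The locus opposite Tmem170b (chromosome 13, 41637397 to 41639942) had 525.5 ± 16.3 reads, against 25 and 21 reads on Tmem170b. Those opposite Snhg11, Map1b, AI593442 and Tmem170b lie entirely within annotated 3' untranslated sequence of these genes, and that opposite Slc1a2 does so for 59.3% of its length.

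Single-exon antisense loci with a mean of at least 10 reads numbered 653, of which 643 had reads in both libraries and 28 differed between them by exact binomial tests with Benjamini-Hochberg adjustment. The 20 most abundant genes had 0.197 single-exon antisense reads per 1000 sense reads, and the genes opposite 9 of the 10 loci with most reads had 1128. The other locus lies opposite no annotated gene. Spliced antisense reads were not counted. Single-exon models held 95.5% and 95.6% of the reads on unannotated antisense genes in replicate 1 and replicate 2. A spliced read taken in the wrong direction would not enter the single-exon count, so the rate of the 20 genes could be low for that reason. The 9 loci were also picked for their antisense reads. The comparison thus does not decide whether sense reads were taken in the wrong direction, for these or for the other loci. Of the loci, 186 end inside an exon of the sense gene and could be searched. Of these, 40.3% (95% interval 33.2 to 47.7%) had an A-rich stretch past their 3' end, where priming of the antisense strand may start. The upper bound lay under the 50% set in advance for priming as the source of these loci as a set. How many primed loci the search would miss was not measured, so this bound does not decide whether priming is their source. The share with an A-rich stretch was 9.62 times the 4.19% found at random positions of the same transcripts, which leaves priming open. The polyadenylation signals AATAAA and ATTAAA are argued against as the source of these ends as a set. Of the loci, 2.15% (0.589 to 5.41%) had one in their last 40 bases against 4.68% at random positions. Only the end of the model with most reads was searched at each locus. Other signals were not searched, and how many true ends the search would miss was not measured. The origin of the loci stays open, no biological explanation other than such a signal was tested, and the loci that end outside annotated exons could not be searched.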

How the results depend on the processing

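Giving each shared intron chain to 1 gene, leaving out the most abundant member of a list and running 1000000 permutations were chosen only after the results were seen. No paired analysis was possible because there is only 1 group. The cause of the changes below was not tested unless it is stated. Of 120 planned values of the 20 genes named as differing, 24 could not be had because the gene fell under the read minimum, 12 of them on known transcripts only, 9 with at least 50 reads and 3 without the genomic class. Of the other 96, 95 kept their direction and their side of the threshold, and Zfas1 lost its call where genes of any depth were tested. The log2 ratio of Cyp2a5 moved from 3.95 to 6.09 on known transcripts only, where replicate 2 had 0 reads and the value rests on the 0.5 added to each count. The share of calls higher in replicate 1 was 53.3%, 48.1% with TMM scaling and 59.7% with median-of-ratios scaling, and the number of calls ranged from 374 without a read minimum to 519 without the genomic class, apart from the 2-fold minimum. With that minimum 95 genes differed, 53 higher in replicate 1 and 42 in replicate 2. With each shared chain given to 1 gene, 413 genes differed, all of them among the 439, the log2 ratio of Gm27221 went to -0.30 and that of Gm43738 to 0.23, and Spearman rho was 0.9496. Pearson r and rho were 0.971 and 0.968 for genes with at least 20 reads, 0.969 and 0.944 on known transcripts only, and 0.973 and 0.952 without the genomic class.

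Of 147 ratios of lists, 128 kept their direction and their side of the threshold. On known transcripts only, the ratio was 1.02 for astrocyte markers (call lost), 1.18 for mural cell markers (call gained) and 0.985 for striatum markers (reversed, with no call in either). With TMM scaling it was 1.02 for astrocyte and 1.06 for inhibitory neuron markers (calls lost). With median-of-ratios scaling it was 1.15 for mural cell, 1.13 for oligodendrocyte precursor and 1.03 for synaptic genes, and without the genomic class 1.58 for hippocampus and 1.09 for striatum markers (calls gained). Without the most abundant member, calls were lost for choroid plexus (0.616), cortical layer (0.966, reversed), stress (0.917, reversed), inhibitory neuron (1.05) and thalamus markers (1.38), and gained for hippocampus (1.78), oligodendrocyte precursor (1.29), striatum (1.09) and synaptic genes (1.10). Levels of lists moved by less than their SD in 108 of 126 values. Values from each library alone lie within 1 SD of the mean by construction and are left out here and for exons.

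Without single-exon models, known transcripts took 78.8% of reads, unannotated combinations 7.43%, unannotated splice sites 4.22%, genomic 0.0799%, antisense 0.0825% and intergenic models 0.0331%, since the last 3 classes are mostly single-exon. Shared chains rose with depth. With at least 2 reads in the library of origin they were 77.4% of incomplete matches, 78.2% of unannotated combinations, 68.3% of unannotated splice sites, 63.9% of genomic, 65.7% of antisense and 59.6% of intergenic models, and with at least 5 reads 97.8%, 98.1%, 97.2%, 92.8%, 96.7% and 94.4%. With intron ends matched within 5 bases they were 48.5% of unannotated combinations, 38.6% of unannotated splice sites, 20.6% of antisense and 13.5% of intergenic models. The median share of the most abundant transcript was 98.2% with at least 50 reads per library, 81.1% with unannotated complete chains included and 66.1% with all models, where 122 and 35 genes differed in usage. With 1000000 permutations 6 genes differed on annotated transcripts, so the smallest p of the planned permutations set the count of 0. On known transcripts only, 40 exons were alternative, as fewer models enter, and 3 differed instead of 2. Exon inclusion moved by less than its SD in 66 of 118 values. Depth limits what can be seen, and the exact binomial test recovered 59.4% of simulated 2-fold changes.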

Other observations

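The genes of the first paragraph below and the count of differences ended by reads on other genes were chosen only after the results were seen, while the tests of tissue lists and of the same reads on other genes in the paragraph on hormone genes were written before.

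Among the 95 genes that differed at least 2-fold, these were picked singly from outside the fixed lists, and no group of them was tested. Ifit3 had 121 reads in replicate 1 against 47 in replicate 2, Ifit3b 60 against 19, Ifit1 28 against 6 and Oasl2 22 against 1. Ifit3 and Ifit3b are similar copies and their counts could share reads. Ptgds, the prostaglandin D synthase gene of the meninges and choroid plexus, had 1489 reads in replicate 1 and 533 in replicate 2, and the matrix genes Fmod and Pcolce had 34 against 7 and 28 against 7. The ribosomal protein genes Rps21 and Rps27 had 68 against 151 and 67 against 120.

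Gh, Prl, Omp, Bpifb9a, Bpifb9b and Cyp2a5 stood out in replicate 1, and their tissues lie near the brain. A different assignment of the same reads in replicate 2 is argued against for models on the same strand that overlap by at least 80% both ways. Of the 1070 reads of these genes in replicate 1, 0% had such a counterpart on other genes in replicate 2. RNA from pituitary tissue may have entered replicate 1, since 10 other pituitary genes, of which 8 had reads and 0 exceeded 100 CPM in this cortex, had 14 reads in replicate 1 against 2 in replicate 2 (6.23-fold, 95% interval 1.43 to 56.4). Of the 8, 7 were higher in replicate 1 and Lhb (1 against 2) went the other way, and none had more than 5 reads in a library. Pomc and Cga, abundant in that gland, had only 2 and 5 reads in replicate 1, beside 393 of Gh and 415 of Prl. RNA from nasal tissue may also have entered it, since 19 other nasal genes, of which 15 had reads and 0 exceeded 100 CPM, had 127 against 59 reads (1.91-fold, 1.40 to 2.65), with 13 of the 15 higher in replicate 1 and Gng13 (26 against 40) and Ano2 (5 against 9) the other way. Carry-over from a library of another tissue was not tested and stays open, and no biological explanation was tested.

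Part of the differences of at least 2-fold could come from reads at the same positions that were given to different genes in the libraries. Adding the reads on other genes ended 17 of the 95 differences, and 7 of the 20 named ones, Klhl10, Hgs, Zfp454, 4930520O04Rik, Gm27221, Gm21955 and Gm43738. Klhl10 went from a log2 ratio of 5.56 to 0.20 (exact binomial p 0.446 after) when 60 reads on other genes of replicate 2 were added, and Hgs from -3.37 to 0.27 (p 0.0641) when 213 reads were added. Only models on the same strand that overlap by at least 80% both ways were searched, so reassigned reads of other lengths could be missed. Pcdhga3 was not among the differences ended in this way. Its log2 ratio nevertheless went from 5.76 to 1.12, and it lost its call, when shared intron chains were given to 1 gene. The assignment of reads thus stays open for the 17, for Pcdhga3 and for the other differences.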
